A study of Mus musculus with 6 samples.

How the data were processed

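RNA levels were measured in fully differentiated primary fat cells of the mouse inguinal depot on 6 Affymetrix MoGene 2.0 ST arrays, whose probes cover the exons of annotated genes. Per the labels' protocols, total RNA was amplified into sense-strand DNA with the Affymetrix WT Plus kit, fragmented and labelled with biotin. The 3 arrays of PBS-treated cells and the 3 arrays of cells treated with 50 µM kynurenic acid for 12 h were grouped by their titles. The titles call the replicates technical and nothing says that they came from separate cultures or animals, so every p-value measures only the spread between these arrays, which may be technical.

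The deposited log2 values were made by the authors with RMA, which subtracts background, gives all arrays the same distribution of probe values and summarises the probes of each transcript cluster by median polish, per the file headers and the submitters' processing notes, which name Affymetrix Expression Console 1.41. The log2 values were rounded to 2 decimals in the deposited tables. A shared distribution removes overall differences in brightness between arrays, so a change of most transcripts in 1 direction would not be seen. Per the file headers, the annotation was NetAffx build 34 on the mm10 genome, and all coordinates given are those of that annotation. The authors' deposited table also gives the mean linear intensity of each group, a signed fold change of those means, a p-value from Student's t-test and a q-value whose method is not given in the sources used here. Both deposited tables held the same array values, with a largest difference of 0 over 41345 transcript clusters, so that no alternative from the other table could be computed. Values ran from 1.38 to 13.18 on the log2 scale.

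Of the 41345 clusters, 29726 carried a gene symbol and 11619 did not. A single row per gene was kept for 27365 symbols, the cluster with the highest mean over all 6 arrays, chosen without regard to group; 1574 symbols had several clusters. For Ahr, Ftl1 and Ywhaz this rule took a cluster whose probes are annotated as matching other transcripts as well, and the values of the other clusters are given where they differ. Symbols are those of the array annotation. Through Entrez identifiers, 23546 genes (86.0%) were found in a RefSeq gene table of assembly GRCm38.p6, where 1743 carried another symbol. No filter on dim genes was used in the main test. The main test used none of the clusters without a symbol. Such clusters entered only the control probe sets, the alternative with every annotated cluster as its own row and the counts from the authors' table.

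Kynurenic acid was compared with PBS by limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3) on the log2 values of all 6 arrays without covariates, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 for the adjusted p; the test was two-sided. A size threshold of 1.5-fold was added. Log2 changes are kynurenic acid minus PBS, and intervals are 95% intervals of the limma fit. The number of arrays limits the precision, and the median 95% interval reached 0.21 log2 to either side.

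The 28 gene lists were written from textbook knowledge. They were named thermogenic, lipolysis and lipid droplet, fatty acid oxidation, oxidative phosphorylation, TCA cycle, lipogenesis and triglyceride synthesis, cholesterol synthesis, adipocyte identity, preadipocyte and fibroblast, extracellular matrix remodelling, macrophage markers, lymphocyte markers, endothelial markers, skeletal muscle markers, epithelial and mammary markers, inflammatory cytokines and NF-kB targets, anti-inflammatory and type 2, interferon-stimulated, aryl hydrocarbon receptor targets, NRF2 and antioxidant, unfolded protein and integrated stress response, immediate early and cAMP-responsive, hypoxia and glycolysis, cell cycle, kynurenine pathway and receptors, G protein and RGS signalling, circadian clock, and reference genes. Each was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. An adjustment of the members' limma p-values over each list alone stands beside the count over all genes.

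Genes were named by a fixed rule. Gpr35, Ahr, Rgs14, Cyp1a1, Cyp1b1, Ppargc1a, Ucp1, Adrb3, Il6, Tnf and Il10 were named whatever their values. Up to 10 genes per direction were to be taken from those past the test with groups that did not overlap and a level at or above the 40th percentile in the higher group. No gene passed, so the rule's fallback applied: the 5 smallest unadjusted p-values per direction under the other conditions, described as not past the test. Predicted, uncharacterised, small RNA, receptor segment, Olfr and Vmn genes were left out of that choice. From each list, the 2 members with the largest absolute change at that level were named as values, except that 1 is given for the lipolysis and lipid droplet list. The lists, the rule, the test and its alternatives were set before the data were examined, apart from the additions named as later.

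Alternatives were filters at the 40th and 60th percentile of mean level, centring each array on its median, cyclic loess, leaving out each array in turn, the replicate number as a block, an intensity trend, robust moderation, array weights, the methods' t-test, the mean of all clusters of a gene, every annotated cluster as its own row, leaving out the uncharacterised and receptor family genes, a minimum change of 1.2-fold, an adjusted p of 0.01, an estimated inter-gene correlation for camera, and fry. Gene lists were not rerun with robust moderation, the methods' t-test, the 1.2-fold minimum, the stricter threshold or separate clusters. The estimated correlation gave larger p-values even where the estimate was below the preset 0.01. For the endothelial markers, at an estimate of 0.00058, camera's unadjusted p rose from 0.0258 to 0.0776. A call lost with that setting is thus not put down to correlation alone. Added after seeing the data were a comparison without both arrays numbered 2 and a comparison of kynurenic acid array 2 alone with the 3 PBS arrays, which assumes that the single array varies like the PBS arrays.

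The test was tried on simulated data for the comparison of kynurenic acid with PBS, with the means and spreads of the 27365 genes and 200 changed genes. It recovered 6% of the genes changed 1.2-fold, 94% of those changed 1.5-fold and 100% of those changed 2-fold or 3-fold, 50 genes of each size, and also called 9 unchanged genes. In 20 simulated data sets with the 28 measured cell cycle genes shifted by -0.2 log2, camera called that list in 20, and in 20 without a shift it called 0 of 560 lists. The simulated genes varied independently of each other, which real genes do not. All 200 changed genes were planted in a single data set, where calls of the larger changes ease the Benjamini-Hochberg threshold for the rest. With fewer changed genes the share recovered at 1.5-fold would be lower, so a count of 0 calls does not exclude changes of that size.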

Results

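Transcript levels were recorded in cultured primary adipocytes of mouse inguinal fat, a subcutaneous white depot, 12 h after addition of kynurenic acid or of PBS as the control. Kynurenic acid is a breakdown product of tryptophan formed from kynurenine, and Gpr35 and Ahr encode receptors reported to bind it. The data were 6 arrays, 3 of cells given 50 µM kynurenic acid and 3 of PBS-treated cells, with 27365 genes tested. Array medians lay between 3.93 and 3.98 log2, and Pearson correlations across genes between pairs of arrays were 0.993 to 0.996, where genes are not independent replicates. The comparison asks which transcripts differed after this acute treatment.

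Cell cycle transcripts were lower as a group with kynurenic acid by camera at its preset correlation (adjusted p = 1.16e-08). The call was lost at adjusted p = 0.218 with an estimated correlation. With fry, which tests the list against no change and not against other genes, it did not pass (adjusted p = 0.0959). No single gene passed the limma test over all genes. The cell cycle list, which holds genes of DNA replication and mitosis, had a median log2 change of -0.18 over 28 measured genes, 26 of them below 0 and 1 above. Kif11, a kinesin that separates the spindle poles, measured 4.69 ± 0.19 log2 with PBS and 4.16 ± 0.11 with kynurenic acid (SD, n = 3 each), a fold of 1.44 downward. Top2a, the topoisomerase that untangles replicated DNA, measured 5.09 ± 0.067 and 4.69 ± 0.16 (SD, n = 3 each).

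Of the 28 cell cycle genes, 0 passed the limma test over all genes, 12 were lower at an unadjusted p below 0.05, and 6 fell when adjusted over the list alone. The smallest adjusted p over the list alone was 0.0248 for Kif11, which was lower in 3 of 3 kynurenic acid arrays than in any PBS array. The other members that fell over the list alone were Top2a, Bub1, Mki67, Rrm2 and Tpx2. Of these, Bub1, Mki67, Rrm2 and Tpx2 were singled out after their values were seen. Their log2 changes were -0.39 for Bub1, a spindle checkpoint kinase, -0.35 for Mki67, a proliferation marker, -0.33 for Rrm2, a subunit of ribonucleotide reductase, and -0.31 for Tpx2, a spindle assembly factor. Means of the list in the single arrays, as deviations from the mean of all 6, were 0.11, 0.044 and 0.11 for PBS and -0.047, -0.12 and -0.099 for kynurenic acid.

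**Figure D1:**
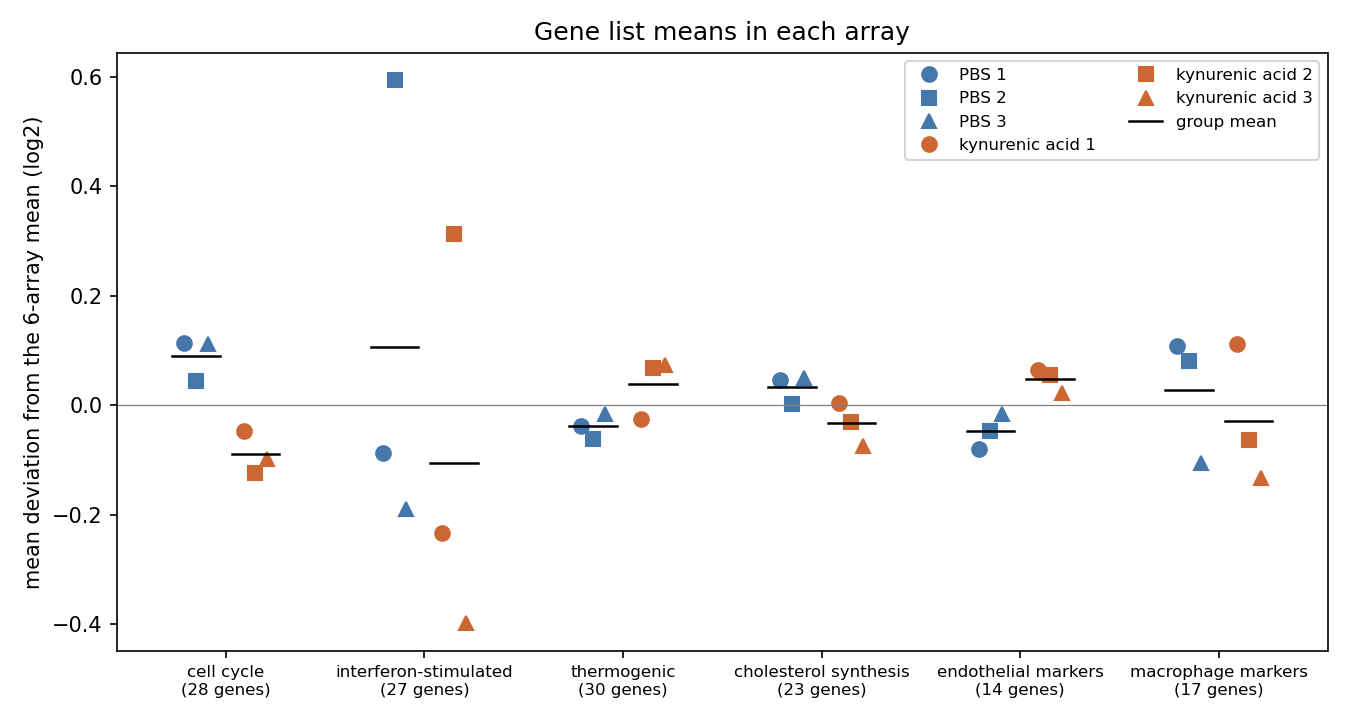
Mean log2 deviation of 6 gene lists from the mean of all 6 arrays, 1 point per array, with blue for PBS, orange for kynurenic acid, the marker shape for the replicate number and a black line for the mean of each group's 3 arrays. Cell cycle means were 0.044 or more in the PBS arrays and -0.047 or less in the kynurenic acid arrays, and the interferon-stimulated list was highest in both arrays numbered 2, at 0.59 and 0.31.

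Among all 27365 genes, limma called 0 changed, 0 higher, 0 lower and 0 changed at least 1.5-fold, with a smallest adjusted p of 0.437. At an unadjusted p below 0.05 there were 2663 genes (9.73%), 1286 higher and 1377 lower. The methods' t-test gave 2165 such genes and 0 after Benjamini-Hochberg adjustment. Both groups were free of overlap in 14.8% of genes, where chance gives 10% for 3 arrays against 3. Whatever their p, 37 genes differed at least 1.5-fold, 9 upward and 28 downward.

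Among the genes that the rule for naming admitted, those with the smallest unadjusted p in each direction did not pass the test either, and their values are given as measured. On the higher side were Cdh5, which encodes the endothelial junction protein VE-cadherin, with a log2 change of 0.51, Mettl7a3 with 0.80, the transcription factor Foxd3 with 0.45, Ciita, the activator of MHC class II genes, with 0.50, and Lyrm9 with 0.38. On the lower side were Kif18a, a kinesin that aligns chromosomes in mitosis, with -0.62, Csprs with -0.86, Lrrc1 with -0.55, Als2cr12 (now Flacc1) with -0.52 and Cep44, a centrosomal protein gene, with -0.45. Kif18a, Csprs, Lrrc1 and Cep44 read below the mean of the antigenomic background probe sets in all 3 kynurenic acid arrays. The sizes of their changes are thus not measured above background. Standard errors of these 10 changes lay between 0.078 for Lyrm9 and 0.14 for Mettl7a3, and all 10 adjusted p-values were 0.437 or 0.471. Kif18a lies on chromosome 2 at 109280738 to 109341747 and Cdh5 on chromosome 8 at 104101625 to 104144504, and the Csprs cluster is on a separate contig assigned to chromosome 1.

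**Figure D2:**
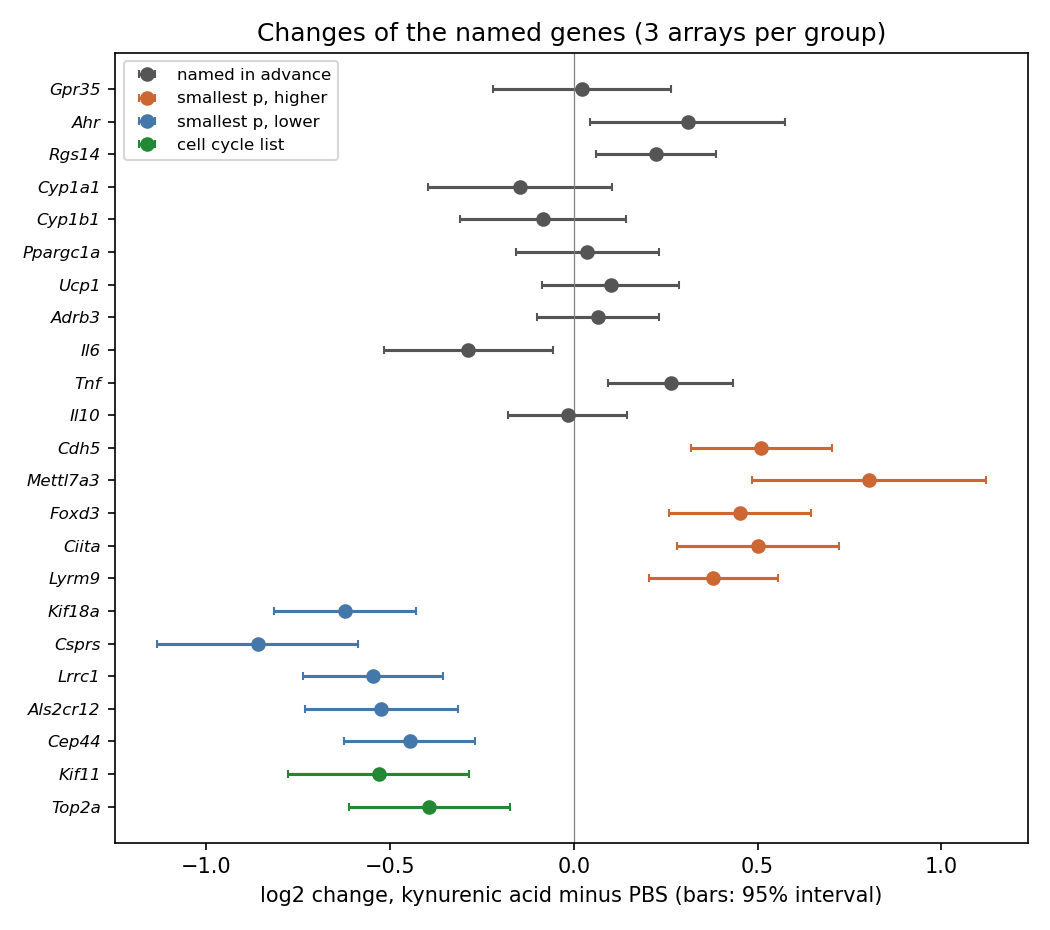
Log2 change with kynurenic acid minus PBS for the genes named in advance (grey), the 5 genes with the smallest unadjusted p under the naming rule upward (orange) and downward (blue) and the 2 named cell cycle genes (green), with bars for the 95% interval of the limma fit over 3 arrays per group. Als2cr12 at -0.52 and Cdh5 at 0.51 lie away from 0, Gpr35 at 0.023 lies close to 0, and no adjusted p was below 0.437.

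Gpr35 measured 5.15 ± 0.18 log2 with PBS and 5.17 ± 0.10 with kynurenic acid (SD, n = 3 each), a change of 0.023 with a 95% interval from -0.22 to 0.27. Rgs14, a regulator of G protein signalling on chromosome 13 at 55369732 to 55384687, measured 4.52 ± 0.045 and 4.75 ± 0.012 (SD, n = 3 each). Its limma p was 0.0130 and 0.474 after adjustment. Clusters under the symbol Ahr disagreed. A cluster of 4 probes that also match other transcripts gave 0.31 (SE 0.12, adjusted p = 0.493). It is annotated to the plus strand and only to 35534971 to 35535030, so its value may not be that of Ahr transcripts. The cluster of 30 probes over the whole gene, on chromosome 12 at 35497974 to 35535038, gave -0.083 (unadjusted p = 0.561). Cyp1a1 and Cyp1b1, enzymes induced through the aryl hydrocarbon receptor, had log2 changes of -0.15 (SE 0.11) and -0.083 (SE 0.10), with Cyp1a1 below the background probe sets in all 3 kynurenic acid arrays. None of the 14 measured members of the aryl hydrocarbon receptor targets list passed over all genes or over the list alone. Its median was 0.065 (camera adjusted p = 0.166) and ran from 0.019 without kynurenic acid replicate 1 to 0.12 without kynurenic acid replicate 2, with Slc7a5 at 0.24. The kynurenine pathway and receptors list, 22 genes that include Slc7a5 and Ahr, had a median of 0.028 (adjusted p = 0.320), which turned to -0.0083 after centring the arrays on their medians. For the G protein and RGS signalling list of 33 genes the median was -0.01 (adjusted p = 0.562), with Rgs14 at 0.22 and the adenylyl cyclase gene Adcy6 at 0.20. Neither list had a member past the test over all genes or over the list alone. At an unadjusted limma p below 0.05 stood 4 higher genes of the aryl hydrocarbon receptor targets list, 1 higher gene of the kynurenine list and 2 higher and 2 lower genes of the G protein list. The cluster of 4 probes under the symbol Ahr, which may not read its transcripts, was 1 of the 4 and the 1 gene of the kynurenine list.

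Genes of heat production were not past the list test at the main setting. The thermogenic list had a median log2 change of 0.07 over 30 genes, 23 above 0, with camera adjusted p = 0.0566 and adjusted p = 0.612 with an estimated correlation. None of its genes passed limma over all genes or over the list alone, and 4 were higher and 1 lower at an unadjusted p below 0.05. The list passed in 9 of 19 alternatives, with medians from 0.033 to 0.13 and adjusted p from 0.00457 to 0.612 over the 19. Passes included 0.0278 after cyclic loess, 0.0427 after median centring, 0.00457 and 0.0106 at the filters at the 40th and 60th percentile, and 0.00513 without kynurenic acid replicate 1. Ucp1, the uncoupling protein of brown and beige fat, measured 3.37 ± 0.07 with PBS and 3.47 ± 0.087 with kynurenic acid (SD, n = 3 each), below the 3.58 to 3.91 array means of the antigenomic background probe sets. Ppargc1a, a coactivator of mitochondrial genes, had a change of 0.037 log2 with an interval from -0.16 to 0.23. Adrb3, the main beta-adrenergic receptor of mouse fat, had 0.067 with an interval from -0.099 to 0.23. Tnfrsf9, a marker used for beige adipocytes, had a change of 0.35 (SE 0.09, adjusted p = 0.471), and Esrra, a nuclear receptor that acts with Ppargc1a, had -0.31 (SE 0.12, adjusted p = 0.493).

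Lists of lipid and energy metabolism had no member past the test over all genes or over the list alone. The cholesterol synthesis list had a median of -0.07 over 23 genes, 17 below 0, with camera adjusted p = 0.0566. The 2 largest changes were -0.25 for Idi1 and -0.23 for Stard4. It passed in 6 of 19 alternatives. Passes included 0.0427 after centring arrays on their medians, 0.0120 with the intensity trend, 0.0246 without PBS replicate 2 and 0.0176 without kynurenic acid replicate 1. It gave 0.612 after cyclic loess, within a range from 0.0120 to an adjusted p = 0.814 with an estimated correlation. The oxidative phosphorylation list had a median of 0.02 (51 genes, adjusted p = 0.459, Cox5b at 0.28 and Atp5d at 0.27). The Atp5d value came from a cluster annotated to the minus strand at 80145218 to 80145811. An Atp5d cluster of 33 probes from 80138632 to 80145818 gave 0.063. The list passed at a median of 0.064 after cyclic loess (0.0284), of 0.02 at the 60th percentile filter (0.0475) and of 0.067 without kynurenic acid replicate 1 (0.0422), within a range from 0.0284 to 0.982. It did not pass at adjusted p = 0.882 with an estimated correlation. Its median turned to -0.017 after median centring. Medians were -0.027 for the TCA cycle (20 genes, adjusted p = 0.320, Pdhb at -0.23 and Suclg2 at -0.18, against 0.083 in a dimmer cluster). They were -0.043 for fatty acid oxidation (24 genes, adjusted p = 0.320, Cpt1a at -0.18 and Acads at 0.13, with Acot2 as far below 0), and from -0.074 to 0 with single arrays left out. Lipogenesis and triglyceride synthesis had 0.005 (24 genes, adjusted p = 0.562), with Acacb, an acetyl-CoA carboxylase gene, at 0.31 and Agpat9 at -0.17. This list passed at 0.0475 at the 60th percentile filter, within a range from 0.0475 to 0.892, and did not pass at adjusted p = 0.821 with an estimated correlation. Lipolysis and lipid droplet genes had 0.033 (19 genes, adjusted p = 0.780), with the lipid droplet gene Plin5 at 0.22. Adipocyte identity genes had -0.038 (20 genes, adjusted p = 0.689), with the leptin gene Lep at -0.20 and Klf15 at 0.19. At an unadjusted limma p below 0.05 stood 3 lower cholesterol genes, 1 higher and 2 lower oxidative phosphorylation genes, 1 lower TCA cycle gene, 1 higher gene each of lipogenesis and lipolysis, and 0 of fatty acid oxidation and adipocyte identity. The lipogenesis and lipolysis medians turned below 0 after median centring, and the TCA cycle median turned above 0 after cyclic loess.

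Interferon-stimulated transcripts were high in PBS array 2 and in kynurenic acid array 2. The list of 27 genes had a median log2 change of -0.21 and camera adjusted p = 0.0106, with 26 genes below 0, 0 past the test over all genes, 0 over the list alone and 0 at an unadjusted p below 0.05. Its call was lost at adjusted p = 0.814 with an estimated correlation. List means in the single arrays were -0.087, 0.59 and -0.19 with PBS and -0.23, 0.31 and -0.40 with kynurenic acid. Without PBS replicate 2 the median turned to 0.017 (adjusted p = 0.853), and without kynurenic acid replicate 1 it was -0.15 (0.0868). Without kynurenic acid replicate 3 it was -0.073 (0.543). The median was -0.34 (4.37e-06) without PBS replicate 3 and -0.41 (9.66e-08) without kynurenic acid replicate 2. Its adjusted p ranged from 6.25e-09 to 0.853 over its alternatives. The value of 6.25e-09 was that with the replicate number as a block, at a median of -0.21, where the list means of same-numbered arrays differed by -0.15, -0.28 and -0.21. Ifi44 measured 6.59 ± 0.63 with PBS and 6.15 ± 0.76 with kynurenic acid, and Mx2, annotated as a transcribed pseudogene, 4.39 ± 1.01 and 3.99 ± 0.44 (SD, n = 3 each).

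Cytokine genes showed values on both sides of 0 and none passed. Tnf, an inflammatory cytokine gene, measured 4.62 ± 0.067 with PBS and 4.88 ± 0.02 with kynurenic acid, Il6 4.32 ± 0.15 and 4.03 ± 0.12, and Il10, an anti-inflammatory cytokine gene, 2.67 ± 0.038 and 2.65 ± 0.01 (SD, n = 3 each). Their adjusted limma p-values were 0.471 for Tnf, 0.474 for Il6 and 0.955 for Il10. The inflammatory cytokines and NF-kB targets list had a median of -0.018 over 30 genes (camera adjusted p = 0.562), with 4 genes higher and 4 lower at an unadjusted p below 0.05, and the chemokine genes Cxcl10 at -0.48 and Ccl8 at -0.46. The anti-inflammatory and type 2 list had a median of 0.047 over 19 genes, 1 of them lower at an unadjusted p below 0.05, while its mean and camera's direction were below 0 (adjusted p = 0.855), with Il13ra1 at -0.26 and Mrc1 at -0.17. In neither list did a member pass over all genes or over the list alone.

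Markers of other cells that a fat culture can hold were measured beside these groups. Of the 14 endothelial markers, 1 rose when adjusted over the list alone, Cdh5, which measured 5.08 ± 0.09 with PBS and 5.59 ± 0.084 with kynurenic acid (SD, n = 3 each), higher in 3 of 3 kynurenic acid arrays than in any PBS array. Its limma p was 0.00275 adjusted over the list alone and 0.471 over all genes. Other Cdh5 clusters, annotated to sequence records and not to a chromosome, had values identical to each other, below background, and gave -0.0067. Their probes also match other transcripts. The endothelial list had a median of 0.088 (camera adjusted p = 0.144), with Esam at 0.25. Preadipocyte and fibroblast markers had a median of -0.027 over 21 genes (adjusted p = 0.320), with Lum at -0.33 and Cd55 at -0.23. Extracellular matrix remodelling genes had -0.0017 over 38 genes (adjusted p = 0.562), with Adamts4 at 0.29 and Mmp3 at -0.22. Macrophage markers had a median of -0.0033 over 17 genes (adjusted p = 0.418), with Ptprc at -0.31 and Cd14 at -0.27, and passed without kynurenic acid replicate 1 at a median of -0.073 (0.0349). At an adjusted p = 0.870 with an estimated correlation the macrophage list did not pass. Their abundant transcripts Lyz2 and Cd68 stood at 10.58 and 9.77 log2 with PBS, named after their values were seen. Medians were 0.057 for lymphocyte markers (19 genes, adjusted p = 0.147, Cd8b1 at 0.21 and Prf1 at 0.15), 0.10 for skeletal muscle markers (12 genes, adjusted p = 0.191, Ckm at 0.31 and Myl1 at -0.18) and 0.062 for epithelial and mammary markers (14 genes, adjusted p = 0.244, Krt18 at 0.19 and Cdh1 at 0.18, against -0.013 in a dimmer cluster). Apart from Cdh5, no marker passed over all genes or over its list alone, and after cyclic loess the matrix and macrophage medians turned above 0. At an unadjusted limma p below 0.05 stood 1 higher endothelial, 2 higher lymphocyte, 1 higher muscle, 2 higher epithelial, 1 lower preadipocyte, 2 lower matrix and 0 macrophage genes.

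Stress, clock and reference genes were also without a member past the test over all genes or over the list alone. The unfolded protein and integrated stress response list had a median of -0.042 over 34 genes (camera adjusted p = 0.147), with the folate enzyme genes Mthfd2 at -0.31 and Aldh1l2 at -0.25. NRF2 and antioxidant genes had -0.03 over 27 genes (adjusted p = 0.320), with Slc7a11 at -0.21, against -0.03 in a dimmer cluster. The ferritin gene Ftl1 had 0.40 in a cluster on chromosome 11 whose probes also match other transcripts. On chromosome 7, a Ftl1 cluster of 13 specific probes gave -0.22 and a cluster of 8 less specific probes gave 0.31. The 0.40 may thus not be that of Ftl1 transcripts. Hypoxia and glycolysis genes had -0.053 over 26 genes (adjusted p = 0.244), with Eno1 at 0.20 and Ldha at -0.18, and a median of -0.086 without kynurenic acid replicate 2. Immediate early and cAMP-responsive genes had -0.01 over 25 genes (adjusted p = 0.963), with Egr3 at 0.26 and Crem at -0.24. Circadian clock genes had -0.0083 over 18 genes (adjusted p = 0.633), with Bhlhe41 at -0.31 and Nr1d2 at -0.22. The reference genes had -0.057 over 14 genes (adjusted p = 0.147), -0.10 without kynurenic acid replicate 2 and -0.029 without kynurenic acid replicate 3, with Hprt at -0.28 and Ywhaz at -0.25. The Ywhaz value came from a cluster on chromosome 3 whose probes also match other transcripts. A Ywhaz cluster of 24 specific probes, on chromosome 15, gave 0.027. At an unadjusted limma p below 0.05 stood 2 lower stress response, 1 higher NRF2, 1 higher and 2 lower immediate early, 1 lower clock, 2 lower reference and 0 hypoxia genes. The NRF2 gene was Ftl1, by the cluster on chromosome 11 whose probes also match other transcripts. Without both arrays numbered 2, a setting chosen after seeing the data, the stress response list passed at a median of -0.08 and the hypoxia list at -0.11, each at 0.0476, the lowest values of ranges from 0.0476 to 0.994. Neither passed at adjusted p = 0.814 with an estimated correlation. The stress response, immediate early and clock medians turned above 0 after cyclic loess.

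Kynurenic acid arrays 1 and 3 stood apart from the other 4 arrays. The brightest 20% of genes had median deviations from the PBS mean of -0.05 and -0.063 log2 in these 2 arrays and -0.013 in kynurenic acid array 2, and the dimmer 50% of genes had 0.037 and 0.053 in these arrays and 0.01 in array 2. On the first principal component, which held 33.2% of the variance, the PBS arrays lay at -11.9, -14.4 and -5.59, kynurenic acid array 2 at -3.60 and kynurenic acid arrays 1 and 3 at 14.6 and 20.9. Poly-A spike probe sets averaged 6.12 and 6.46 log2 in arrays 1 and 3, 5.89 in array 2 and 5.76 to 5.93 with PBS. In a comparison chosen after seeing the data, kynurenic acid array 2 alone against the 3 PBS arrays gave a cell cycle median of -0.20 (camera adjusted p = 2.82e-08), an interferon-stimulated median of 0.17 and 0 genes past the limma test, with 1371 at an unadjusted p below 0.05. The cell cycle call was lost in the comparison of all 6 arrays at adjusted p = 0.218 with an estimated correlation, which was not used for the single array.

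**Figure D3:**
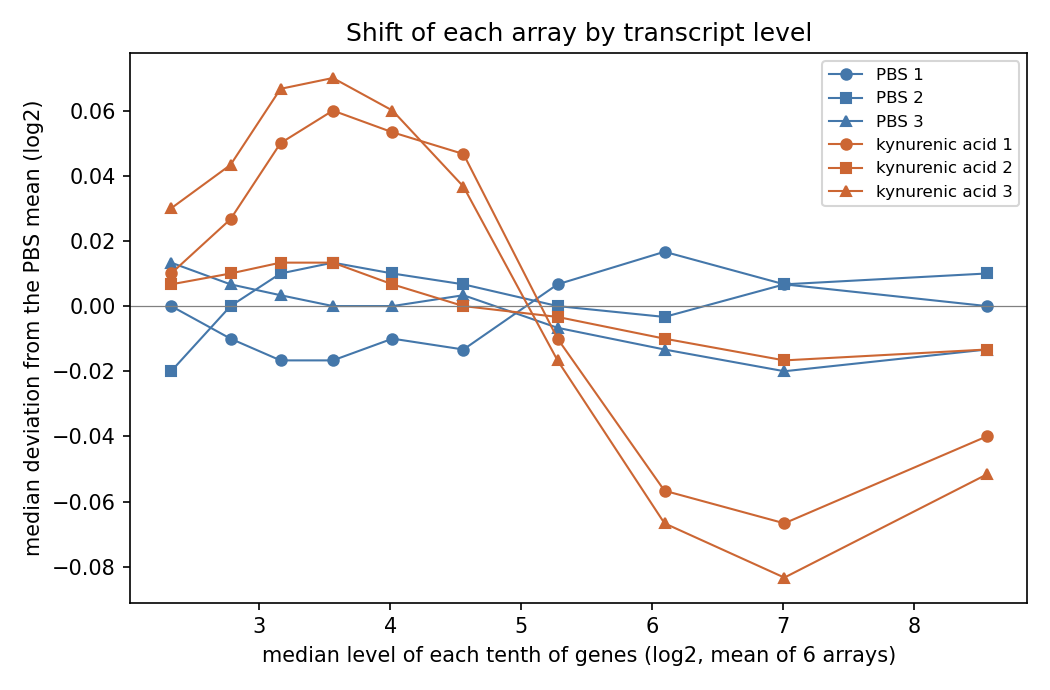
Median log2 deviation of each array from the PBS mean, for 10 equal groups of genes ordered by mean level (log2), with blue for PBS, orange for kynurenic acid and the marker shape for the replicate number. Kynurenic acid arrays 1 and 3 run from above 0 at dim genes to below 0 at bright genes, with slopes of -0.0186 and -0.0241 log2 per log2 unit of level, and kynurenic acid array 2 runs with the PBS arrays.

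The authors' deposited table gave 3018 of 41345 clusters with a p-value below 0.05 and 0 clusters with a q-value below 0.05, the smallest q-value being 0.483. By the fold changes of the authors' deposited table, 556 clusters differed at least 1.5-fold, 176 upward and 380 downward, and 165 of these had a p-value below 0.05. These counts run over all clusters, with those without a symbol and the control probe sets, and use fold changes of linear means. They are thus not comparable with the 37 genes at 1.5-fold by log2 means.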

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

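The tests of the spike controls and of the trend with level were chosen after the result was seen. Apart from the exon and intron controls given last, each of the following control probe set classes lay in a kynurenic acid array above the highest PBS array. The excess was more than the range of the 3 PBS arrays. All of these classes are outside the comparisons. Poly-A spike probe sets averaged 6.12 log2 in kynurenic acid array 1 and 6.46 in array 3, against a highest PBS value of 5.93. ERCC spike probe sets averaged 2.82 in array 1 and 2.84 in array 3, against 2.75. These lay below the antigenomic background means, 3.88 in array 1 and 3.91 in array 3, so they show no spike signal above background. Bacterial hybridisation control probe sets averaged 7.01 in array 3, against 6.94. Reporter probe sets averaged 3.54, 3.47 and 3.53 in arrays 1, 2 and 3, against 3.44, also below the background means of the same arrays. Full-length mRNA rescue probe sets averaged 4.38 in array 3, against 4.24. Probe sets of rRNA averaged 10.91 in array 2, against 10.87, and in array 1 lay below the lowest PBS array, at 10.72 against 10.84. Exon and intron normalisation control probe sets lay below the lowest PBS array in arrays 1 and 3, at 7.18 in each against 7.23 for exons and at 3.50 and 3.49 against 3.55 for introns.

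In kynurenic acid arrays 1 and 3 bright transcripts read lower and dim transcripts higher than with PBS, a trend that bears on every list of bright or dim genes. Less sample RNA per unit of spiked poly-A control is a candidate explanation: the lower of the 2 arrays exceeded the highest of the other 4 by 0.191 log2 in the poly-A probe sets, more than the 0.166 range of those 4, and the hybridisation controls, added later in the protocol, by 0.028. An effect of kynurenic acid on transcript levels stays open, since 2 of its 3 arrays had a slope below the lowest PBS slope by more than the PBS range, and array 2 did not. With 1 array without the trend, the treatment and the preparation of these 2 arrays cannot be told apart.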

How the results depend on the processing

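The comparisons without both arrays numbered 2 and of kynurenic acid array 2 alone were chosen after seeing the data, and the cause was not tested for any difference unless stated. Under all 22 alternatives that tested genes, limma or the methods' t-test called 0 genes, with smallest adjusted p-values from 0.231 to 1, and 0 of the 72 named genes passed. Counts at an unadjusted p below 0.05 moved by over 1.5 times in 3 alternatives. They were 1555 at the 60th percentile filter, with fewer genes, and 81 with the 1.2-fold minimum, with a stricter null. The other was kynurenic acid array 2 alone against PBS, with a single treated array. As a share of the genes tested, the count at the 60th percentile filter was higher than the 9.73% of the main test. Signal over background limits dim genes: Ucp1 and Il10 read below the mean of the background probe sets in all 6 arrays, Cyp1a1, Kif18a, Csprs, Lrrc1 and Cep44 in all 3 kynurenic acid arrays, and Cox5b, Lum, Esam, Ckm and Mx2 in some arrays of the 6. No lymphocyte marker reached the 60th percentile, so this list has no value there.

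Of the list medians under the alternatives, 455 did not turn to the other sign and kept their side of the threshold, and 22 passed only in the alternative. Another 8 lost the call with the same sign and 46 changed sign, 2 of which also lost a call. The 455 include medians of 0, such as fatty acid oxidation and TCA cycle without kynurenic acid replicate 1. Of the values of named genes, 1388 did not turn to the other sign and 16 did. The number of lists called was 4 at the 60th percentile filter, after median centring, after cyclic loess, with the intensity trend and with the mean of clusters, 3 with the uncharacterised and receptor family genes left out, 0 with an estimated correlation and with fry, which has another null, 5 without both arrays numbered 2, and 1 to 5 when single arrays were left out. The cell cycle median stayed between -0.22 and -0.14, with adjusted p from 1.24e-09 to 0.218, and at -0.18 its call was lost with an estimated correlation (0.218) and fry (0.0959). The interferon median was -0.22 at the 40th percentile filter (adjusted p = 0.147), -0.21 at the 60th (0.508), with an estimated correlation (0.814) and with fry (0.742), 0.17 with kynurenic acid array 2 alone, and -0.41 to 0.017 with single arrays left out. Among the arrays numbered 1 and 3, its list means were still lower with kynurenic acid (-0.23 and -0.40) than with PBS (-0.087 and -0.19).

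With the replicate number as a block, 0 genes were called (smallest adjusted p = 0.400), 2919 had an unadjusted limma p below 0.05 and 2 lists were called, and the block changed no call. Deviations of same-numbered arrays correlated across genes at 0.037, 0.068 and 0.094, so the numbers were not taken to pair the samples, although every array correlated best with its own number.

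Other signs turned as follows. At the 60th percentile filter the medians were -0.04 for lipolysis, -0.11 for skeletal muscle, -0.043 for epithelial, -0.083 for anti-inflammatory and 0.01 for clock genes. After median centring they were -0.0033 for lipolysis, -0.017 for oxidative phosphorylation, -0.032 for lipogenesis and -0.0083 for the kynurenine pathway, with Gpr35 at -0.013. After cyclic loess they were 5.5e-05 for the TCA cycle, 0.033 for extracellular matrix, 0.031 for macrophage, 0.0028 for stress response, 0.0021 for immediate early and 0.014 for clock genes. The extracellular matrix median was 0.00057 with array weights and 0.0017 with the mean of clusters, where immediate early was 0.025. Without both arrays numbered 2, lipolysis was -0.04, immediate early 0.025, Gpr35 -0.075, Il10 0.005 and Mx2 0.005. With kynurenic acid array 2 alone, fatty acid oxidation was 0.013, anti-inflammatory -0.013, immediate early 0.03, hypoxia 0.005, G protein signalling 0.01, clock 0.018, Cyp1b1 0.063 and Ifi44 0.42. With single arrays left out, ranges that crossed 0 were -0.012 to 0.07 for anti-inflammatory, -0.021 to 0.0067 for clock, -0.033 to 0.024 for extracellular matrix, -0.04 to 0.027 for immediate early, -0.0042 to 0.062 for kynurenine pathway, -0.0075 to 0.028 for lipogenesis, -0.015 to 0.047 for lipolysis and -0.073 to 0.03 for macrophage genes. Among named genes they were -0.79 to 0.062 for Cxcl10, -0.16 to 0.0033 for Cyp1b1, -0.018 to 0.32 for Eno1, -0.042 to 0.13 for Gpr35, -0.03 to 0.005 for Il10, -0.71 to 0.18 for Mx2, -0.35 to 0.025 for Myl1 and -0.0083 to 0.10 for Ppargc1a.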

Other observations

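The tests on annotation terms, on non-adipocyte cells and on the arrays numbered 2, and the choice of the snoRNA and zinc finger families, were made after the result was seen. Of 1904 annotation terms of 15 to 500 genes, 77 passed camera at a correlation of 0.01, 71 lower with kynurenic acid and 6 higher. Terms of RNA processing were among the lower. With an estimated correlation 0 passed, at a smallest adjusted p = 0.892. That setting raised p even for gene lists with a low estimate, so this loss is not put down to correlation alone. RNA splicing had a median log2 change of -0.077 over 225 genes (adjusted p = 3.00e-05), the spliceosomal complex -0.077 over 138 genes, mRNA processing -0.067 over 290 genes, rRNA processing -0.073 over 100 genes, DNA repair -0.06 over 299 genes and DNA replication -0.087 over 127 genes. After cyclic loess 5 passed, 4 of them also in the main setting and in the same direction: gamete generation (-0.12 over 47 genes, adjusted p = 0.00384), condensed chromosome (-0.10 over 30 genes, adjusted p = 0.0112) and condensed chromosome kinetochore (-0.095 over 76 genes, adjusted p = 0.0243) on the lower side, and transcription regulatory region DNA binding (0.059 over 176 genes, adjusted p = 0.0105) on the higher. The other was activating transcription factor binding (0.13 over 22 genes, adjusted p = 0.0243), also higher. RNA splicing did not pass after cyclic loess, which removes the trend with level in kynurenic acid arrays 1 and 3, and stood at -0.036 (adjusted p = 0.0910).

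Zinc finger genes with Zfp symbols had a median change of -0.05 over 359 genes, 40 lower and 9 higher at an unadjusted p below 0.05, and -0.047 after cyclic loess and -0.087 after median centring. The 76 snoRNA genes had 0.15, 0.19 after cyclic loess and 0.12 after median centring, with single array means of -0.029, -0.32 and 0.15 for PBS and -0.027, 0.17 and 0.054 for kynurenic acid, so that PBS array 2 stood lowest. No test was run on these families.

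The lower cell cycle list was weighed against chance, signal compression and a loss of other cells. Its median of -0.18 lay at percentile 0 of 10000 random lists matched on mean level, whose lowest median was -0.13, and stood at -0.15 after cyclic loess, which argues against compression of bright signals as the whole cause. Fewer non-adipocyte cells with kynurenic acid could lower such transcripts. The preadipocyte and fibroblast list, 20 of whose 21 genes were at or above the 40th percentile of level in these cells, had a median of -0.0267 (95% bootstrap interval -0.08 to 0.047). This median lay above the -0.09 that is 50% of the cell cycle change, but by under the members' SD of 0.13, so a loss of such cells stays open. The 40th percentile, 3.78 log2, lies within the 3.58 to 3.91 array means of the antigenomic background probe sets. Reaching it thus does not show that a marker was detected. The medians of the macrophage (-0.0033), endothelial (0.088), lymphocyte (0.057), muscle (0.10) and epithelial (0.062) lists lay near or above 0. The macrophage mean was -0.055. At or above the 40th percentile were 4 of 19 lymphocyte, 6 of 12 muscle and 8 of 14 epithelial genes. For endothelial and macrophage genes it was 10 of 14 and 17 of 17. Dim genes read higher in kynurenic acid arrays 1 and 3. After cyclic loess the lymphocyte, muscle and epithelial medians were 0.0099, 0.099 and 0.043. Lists with many dim genes thus say little about a loss of such cells. Single arrays moved the list medians. With 1 left out they ran from -0.052 to -0.012 for preadipocyte, -0.073 to 0.03 for macrophage and 0.0575 to 0.11 for endothelial markers. The ranges were 0.023 to 0.087 for lymphocyte, 0.07 to 0.15 for muscle and 0.0225 to 0.11 for epithelial markers. The 10 splits of 6 arrays are too few for a share under 0.05: 1 split, the real one, gave a median of 0.18 in size, with 0.12 as the highest other, while camera at its preset correlation called the list in 4 of the 9 other splits, with a smallest adjusted p of 2.67e-05. The other splits were not free of the treatment. Each put 2 arrays of a group with 1 of the other, so a treatment difference could give part of these calls too. An effect of kynurenic acid on dividing cells of the culture stays open and was not tested.

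Splits of the arrays were also counted for the other results, with the same limit. As many lists as the real 2 were called in 8 of 10 splits, with 7 as the highest other. Each other split puts 2 arrays of a group with 1 of the other, so it keeps a part of any treatment difference. That part could give such calls. Structure among the arrays apart from the treatment and correlation within lists above the 0.01 set for camera could give them too. No test set these apart. The correlation estimated by camera was 0.785 within the interferon-stimulated list and 0.0382 within the cell cycle list, both above 0.01. The loss of their calls with that setting is not put down to correlation alone, since it raised p at low estimates too. The count of genes past the adjusted threshold was 0 in the real split and 0 as the highest other, and since no count is below 0, the 10 of 10 splits that reach it show nothing. The real split gave 2663 genes at an unadjusted p below 0.05, reached in 1 of 10 splits, with 2180 as the highest other. That other split put kynurenic acid arrays 1 and 3, the 2 with the level trend, in the same group with PBS array 3. The count was 3586 without kynurenic acid replicate 2, and 2093 and 1921 without kynurenic acid replicates 1 and 3. Without single PBS arrays it was 1992, 1947 and 2511. It thus cannot tell the treatment from the shift of those 2 arrays.

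Interferon-stimulated genes were higher in both arrays numbered 2, by a median of 0.63 log2 in PBS array 2 over the mean of PBS arrays 1 and 3, with 25 of 27 genes above both, and by 0.58 in kynurenic acid array 2, with 26 of 27. Both excesses lay above all 10000 random lists matched on level (percentile 100), which argues against repeat hybridisations of 1 RNA per group. More macrophages are argued against by the macrophage list, whose 17 genes had a mean excess of 0.0129 against 0.68 for the interferon list. The macrophage excess was 0.079 in PBS array 2 and -0.054 in kynurenic acid array 2, and the upper 95% bootstrap bound of the mean was 0.080. All 17 were at or above the 40th percentile, a level within the range of the background means, and 1 is in another list. The most abundant of them, Lyz2, stood at 10.62, 10.59 and 10.54 in the PBS arrays. A shared culture or handling of samples with the same number may be the source, and stays open: deviations of same-numbered arrays over the other genes correlated at 0.035, 0.053 and 0.087, above 0 but below 0.1. An effect of kynurenic acid on the list stays open too. With the replicate number as a block, camera at its preset correlation of 0.01 gave adjusted p = 6.25e-09. List means were lower in 3 of 3 same-numbered differences. Without the block, the correlation estimated within the list was 0.785, far above the preset value, and the call was lost at adjusted p = 0.814. No correlation was estimated with the block, so its adjusted p rests on the preset value. Whether the numbers pair the samples is not known.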
